A study of Mus musculus with 4 samples.

How the data were processed

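RNA sequencing libraries of mouse pancreatic duct cells were compared between wild-type animals and animals whose genotype is given as floxed Lats1 and Lats2 with Sox9-CreER. Each group held 2 libraries, taken from the sample titles, and all 4 entered the analysis. Per the labels' protocols, total RNA was extracted with an easy-BLUE kit and 1 µg was made into libraries with a strand-preserving SMARTer kit. How the duct cells were isolated, the age of the mice and the time after Cre induction are not given in the sources used here. Nothing states that the replicates came from separate animals, so p-values measure the spread between these samples. In the libraries labelled knockout this spread may be technical. In wild type it was not only technical, since the female transcript Xist had 362 counts in replicate 1 and 0 in replicate 2.

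The deposited files hold raw read counts per gene model, 1 file per library with 52535 gene models each, in the same order. Per the submitters' processing notes, the genome build was mm10 and the tools named were TopHat and edgeR, without versions. The counting program, its annotation, its use of strand and its treatment of reads that fit several genes are not given in the sources used here. Reads of near-identical genes (trypsins, amylases, haemoglobins, the Hspa1a and Hspa1b pair) may therefore have been split or dropped, and their values are uncertain. The same holds for overlapping gene models. Of the 145 genes named by the rule given further on, 14 overlap another tested model, 5 of them on the same strand and 11 on the opposite strand. By whole-model coordinates, Lats2 overlaps Xpo4, Ctrc Cela2a, Lef1 Gm42449 and Tcf7 Gm26551 on the same strand. Junb overlaps Prdx2, Erfe Ilkap, Slc39a5 Ankrd52, Stk4 Tomm34 and Psmb9 Tap1 on the opposite strand, and the Fgfr2 model spans many neighbours. Whether their exons overlap was not examined.

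Model coordinates in the files count the start from 0 and are given here from 1. Chromosome, start and end then equalled those of GENCODE M21 for 86.8% of the models, and 48178 names were found in that annotation. A spreadsheet had turned 26 gene names into dates, and 23 of these were given their symbol from the coordinates. Cyr61 and Ctgf are the older symbols, used in the files, of Ccn1 and Ccn2.

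Library totals were 3566387 and 4735183 counts in the wild-type libraries (WT 1 and WT 2) and 5082636 and 5925601 in the libraries labelled knockout (KO 1 and KO 2). A floor of 3 counts in a library corresponded to 0.824, 0.674, 0.604 and 0.486 CPM (counts scaled to library size). Folds against a group with 0 counts were computed against 3 counts over the group and are lower bounds. For 1 to 3 counts in a group, the ratio of pooled counts is given with its 95% exact binomial interval. Such bounds and intervals cover counting error only, since the sources used here describe no molecular identifiers.

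Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) in R 4.3.3, with genotype as the only term and all 4 libraries. This left 13990 genes and 2 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values and the threshold was 0.05. Levels are TMM-scaled CPM as mean ± SD, n = 2, and log2 fold changes are knockout-labelled minus wild-type, with the standard error (SE) of the fit.

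Before the data were examined, the design, the alternatives, 43 gene lists and the rule for named genes were fixed. The rule takes Lats1, Lats2, 10 readout genes, and the 8 largest rises and 8 largest falls among changed genes whose groups do not overlap and whose higher group has at least 10 CPM. For each list it takes up to 4 members, namely the 2 with the largest rise and the 2 with the largest fall past the threshold. Unnamed gene models were passed over. Some genes that the rule takes are not reported here. Lists with at least 5 tested members were tested against all other genes with camera (limma 3.58.1, two-sided, preset correlation of 0.01), with Benjamini-Hochberg adjustment over 42 lists. The lists share members: Krt19 is both a duct and a mesothelial gene, for example. Camera was repeated with an estimated correlation and the lists were also tested with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom, so hardly any list could pass. The actin cytoskeleton list, with an estimated correlation of -0.017, went from a camera adjusted p of 2.08e-09 to 0.379. A call lost in that run therefore does not by itself show an effect of correlation between genes. Other lists had estimates up to 0.877 (ribosomal proteins), with 0.836 for the acinar, 0.62 for the smooth muscle and 0.578 for the epithelial junction list. Where genes correlate above the preset of 0.01, camera p-values with the preset can be too small. For such lists that run cannot tell this apart from its few degrees of freedom.

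The procedure was tested on counts simulated from these libraries' means, depths and dispersion, with 200 of 13568 genes changed. In this simulation of the comparison of the 2 groups, edgeR recovered 31% of the 2-fold and 97% of the 4-fold changes, and 8.6% of its calls were false. Camera called a simulated raised list and 0 of 20 unchanged lists. The simulation drew each gene independently and filled the unchanged lists with random genes. It therefore does not show how camera behaves on lists whose genes correlate. It also changed far fewer genes than the 5909 of 13990 called in the data, so its share of false calls may not carry over.

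Other settings, chosen in advance, were the replicate number as a block, RLE and upper quartile scaling, scaling without the acinar list and the 100 most abundant genes, no filter, a filter at a mean of 5 CPM, each library left out, DESeq2 1.42.0, limma voom and glmTreat against a fold of 1.5. A run without 4 ribosomal RNA-like gene models was added after the data were seen, as were lists of hepatocyte, MHC class II, basement membrane and Y-linked genes. A list of lymph node stroma genes was added before its own values were read. When a library is left out, its group holds a single library, which is assumed to vary like the other group. Settings chosen for normalized values (pseudocounts, quantile normalization) were not run, since the files hold counts.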

Results

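Gene expression was measured by RNA sequencing in pancreatic duct cells of C57BL/6 mice, in 2 wild-type libraries and 2 libraries labelled knockout. The knockout genotype combines floxed alleles of Lats1 and Lats2, the kinases that restrain the co-activators YAP and TAZ, with Sox9-CreER, a Cre recombinase that tamoxifen activates in cells expressing Sox9. The comparison asks which genes change in duct cells when both kinases are deleted. Libraries held between 3566387 and 5925601 counts. On log2 CPM, the 2 wild-type libraries correlated across genes at 0.949 and the 2 libraries labelled knockout at 0.967, against 0.760 to 0.781 between the groups (genes are not independent replicates). Counts within each pair differed by more than sampling noise, with a chi-square per degree of freedom of 20.06 (wild type) and 19.98 (knockout-labelled).

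Neither targeted gene was lower in the libraries labelled knockout. Lats1 (mm10, chromosome 10, 7681214 to 7716460) stood at 58.2 ± 10.5 CPM in wild type and 74.6 ± 6.45 CPM in the libraries labelled knockout (SD, n = 2), a log2 difference of 0.36 ± 0.19 SE (edgeR adjusted p = 0.172). Lats1 was at 50.8 and 65.6 CPM in WT 1 and WT 2 and at 70.0 and 79.2 CPM in KO 1 and KO 2. Lats2 (chromosome 14, 57642077 to 57758388) stood at 108 ± 8.53 and 142 ± 29.7 CPM, a log2 difference of 0.40 ± 0.19 SE (edgeR adjusted p = 0.127). Its levels were 114 and 102 CPM in WT 1 and WT 2 and 163 and 121 CPM in KO 1 and KO 2. Without KO 2, Lats2 was higher by 0.63 on the log2 scale (edgeR adjusted p = 0.036), and it also passed when no filter on low counts was applied (0.47, edgeR adjusted p = 0.0433). The counts cover whole gene models, so transcripts from floxed alleles that lose only some exons, and from cells without recombination, are included. The Lats2 model also overlaps a neighbouring gene. These counts therefore do not check the deletion, and the groups are named by their labels throughout.

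Connective tissue growth factor, Krt7, the matrix crosslinking enzyme Lox, 19 of 21 macrophage genes and 18 of 21 matrix protease genes were higher in the libraries labelled knockout. Lower were 16 of 16 T and NK cell genes, 14 of 14 B cell genes, 10 of 14 endothelial genes and 10 of 12 smooth muscle genes (1 smooth muscle gene, Cspg4, rose). These lists passed camera with its preset correlation. The smooth muscle list did not pass fry (fry adjusted p = 0.0751). With an estimated correlation 0 lists passed, but that run has 2 degrees of freedom and hardly any list could pass it. Of 13990 genes tested, 5909 (42.2%) changed (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 3077 higher and 2832 lower. Of these, 1959 were more than 2-fold higher and 2177 more than 2-fold lower. Leaving out 1 library gave 4206 to 4608 changed genes, and without KO 2 the lower genes numbered 1867. Upper quartile scaling moved the median log2 change of all genes from -0.01 to -0.20 and the share of higher genes among those changed from 52.1% to 39.4%. Directions below are relative to TMM scaling unless a scaling is named.

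YAP/TAZ target genes were raised in the libraries labelled knockout. Ctgf (chromosome 10, 24595442 to 24598683), a matricellular protein and standard readout of YAP, rose 38.0-fold, from 33.1 ± 2.24 to 1257 ± 43.8 CPM (SD, n = 2). Cyr61 (chromosome 3, 145646976 to 145649981) rose 2.57-fold, from 341 ± 51.6 to 875 ± 86.8 CPM, and Amotl2, an angiomotin family protein, 6.28-fold. Igfbp3, which binds insulin-like growth factors, rose 9.31-fold. Of 22 tested YAP/TAZ targets, 18 rose and 0 fell, and 19 rose and 0 fell adjusted over the list alone. The list had a median log2 change of 1.37 (camera adjusted p = 1.37e-09, and adjusted p = 0.379 with an estimated correlation). Ankrd1 was at 16.5 ± 13.6 and 96.9 ± 24.9 CPM and did not pass (log2 difference 2.53 ± 0.71 SE, edgeR adjusted p = 0.0662), though it passed with the replicate number as a block. It passed without WT 1 (1.91, edgeR adjusted p = 0.000948) and without WT 2 (3.82, edgeR adjusted p = 5.21e-05).

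Among 24 Hippo pathway components, 15 rose and 4 fell, and 16 rose and 4 fell adjusted over the list alone. Vgll3, a TEAD cofactor, rose 9.35-fold and the scaffold Amot 7.48-fold, while the atypical cadherin Fat4 fell 3.64-fold and the upstream kinase Stk4 2.02-fold. The list's median was 0.82 (camera adjusted p = 0.0012, and adjusted p = 0.379 with an estimated correlation). In the same libraries the macrophage list had a median log2 change of 3.12 and the fibroblast list one of 1.85.

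**Figure D1:**
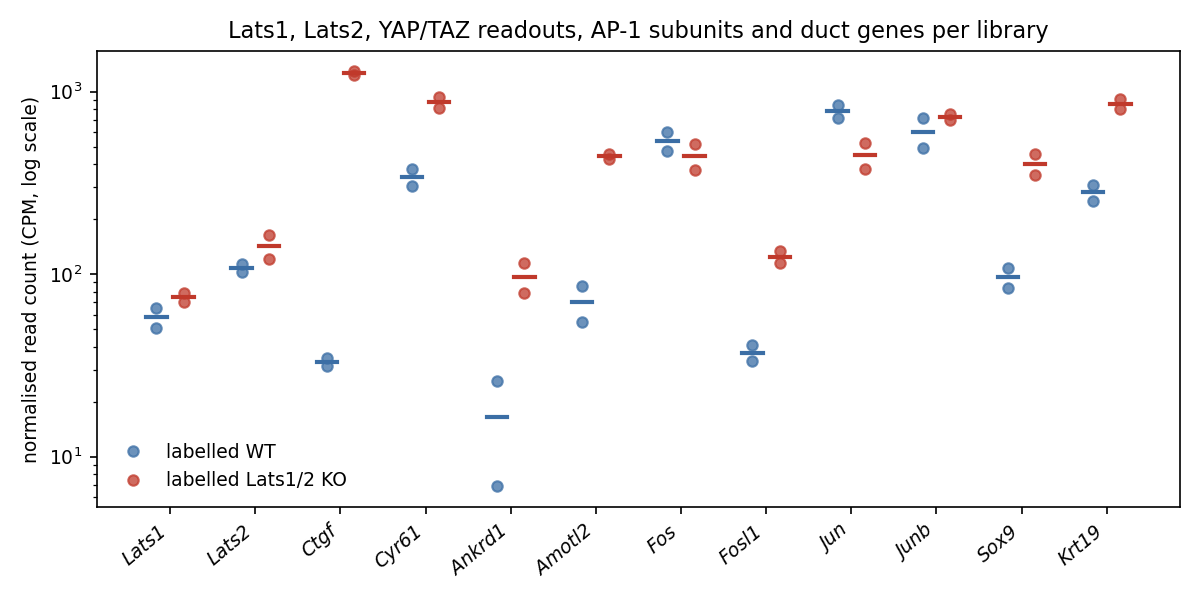
Normalised read counts (CPM, log axis) of Lats1, Lats2, YAP/TAZ readouts, AP-1 subunits and duct genes, with 1 point per library and a bar at the mean of each group's 2 libraries. Ctgf lies at 1226 and 1288 CPM in the libraries labelled knockout and at 34.6 and 31.5 CPM in wild type, while the points for Fos and Junb overlap or lie close together.

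AP-1 subunits, the FOS and JUN family proteins that form the AP-1 transcription factor, moved in both directions. Fosl1 (chromosome 19, 5447703 to 5455945) rose 3.32-fold, from 37.2 ± 5.57 to 124 ± 13.2 CPM, and Jdp2 4.89-fold. Batf3, a transcription factor of dendritic cells, fell 6.77-fold. Batf fell 2.10-fold but did not pass without WT 1 (log2 change -0.91, edgeR adjusted p = 0.0988) or without KO 2 (-0.77, edgeR adjusted p = 0.139). Jun (chromosome 4, 95049034 to 95052222) fell 1.73-fold, from 780 ± 90.1 to 451 ± 104 CPM, and did not pass without WT 2 (-0.66, edgeR adjusted p = 0.131). Fos stood at 535 ± 89.3 and 446 ± 104 CPM and Junb at 602 ± 156 and 727 ± 41.2 CPM, with edgeR adjusted p = 0.346 and 0.331. Of 15 subunits, 6 rose and 3 fell, and 7 rose and 3 fell adjusted over the list alone. The list did not pass (median 0.27, camera adjusted p = 0.244), though it did when no filter was applied (median 0.35, camera adjusted p = 0.0377).

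Genes that respond early to serum or tissue dissociation also split. Klf4 rose 5.26-fold and Rhob 3.39-fold, while the heat shock genes Hspa1b and Hspa1a fell 7.79-fold and 6.85-fold. Of 23 members, 5 rose and 10 fell, and 5 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.409). Without WT 2, 6 fell.

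Duct genes rose together with genes of epithelial junctions. Other tissue was present too: the acinar list took 7.77% and 12.74% of the counts in WT 1 and WT 2, against 0.03% and 0.72% in KO 1 and KO 2. Whether duct RNA took a larger share, duct cells raised these genes or other cells contributed was not tested. The macrophage and fibroblast lists also rose in these libraries, with medians of 3.12 and 1.85. The duct and epithelial junction lists did not pass fry (fry adjusted p = 0.0588 and 0.0746). Krt7, a duct keratin, rose 19.6-fold, from 60.5 ± 0.354 to 1185 ± 239 CPM. Sox9 (chromosome 11, 112782224 to 112787760), the duct transcription factor, rose 4.17-fold, from 96.3 ± 17.3 to 402 ± 73.0 CPM, and Krt19 3.07-fold, from 280 ± 40.1 to 860 ± 75.2 CPM. Spp1 rose 12.9-fold but did not pass without KO 1 (log2 change 3.73, edgeR adjusted p = 0.199) or without KO 2 (3.69, edgeR adjusted p = 0.214), and its change was 4.57 without WT 2. Of 25 duct markers, 15 rose and 2 fell, with the same counts adjusted over the list alone (median 1.20, camera adjusted p = 5.06e-05, and adjusted p = 0.422 with an estimated correlation). The 2 that fell were Car2 and Slc9a3r1, at log2 changes of -0.88 and -0.58. Without KO 1, 0 duct markers fell, and without WT 2, 1 fell. Car2 did not pass without WT 1, WT 2 or KO 1 (edgeR adjusted p = 0.106, 0.0518 and 0.128), nor did Slc9a3r1 (edgeR adjusted p = 0.116, 0.0527 and 0.071).

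Of 23 epithelial junction and polarity genes, 18 rose and 0 fell, and 20 rose and 0 fell adjusted over the list alone. The splicing regulator Esrp1 rose 5.21-fold and the tight junction protein cingulin (Cgn) 4.85-fold (median 1.64, camera adjusted p = 4.26e-08, and adjusted p = 0.502 with an estimated correlation). Among 29 actin cytoskeleton and focal adhesion genes, 23 rose and 0 fell, and 24 rose and 0 fell adjusted over the list alone. The integrin Itga3 rose 7.65-fold (median 1.37, camera adjusted p = 2.08e-09, and adjusted p = 0.379 with an estimated correlation). Without KO 1, and also without KO 2, 1 gene of this list fell.

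Receptor tyrosine kinase ligands, receptors and feedback genes were higher as a list, with members that fell. Epiregulin (Ereg), an EGF receptor ligand, rose 68.6-fold, from 0.612 ± 0.0881 to 44.1 ± 0.0838 CPM. Etv4, a transcription factor downstream of MAPK signalling, had 3 counts in wild type and a pooled ratio of 67.2 (95% interval 22.8 to 328). Egf fell 11.9-fold, with a log2 change of -3.57 that was -2.85 without WT 2, -2.89 without KO 1 and -5.20 without KO 2. Fgfr2 fell 1.52-fold and did not pass without WT 2, KO 1 or KO 2 (edgeR adjusted p = 0.238, 0.181 and 0.0523). Of 28 receptor tyrosine kinase ligands, receptors and feedback genes, 18 rose and 2 fell, and 20 rose and 2 fell adjusted over the list alone. The list's median was 1.36 (camera adjusted p = 1.89e-07, and adjusted p = 0.422 with an estimated correlation). Without WT 2, KO 1 or KO 2, 1 of its genes fell.

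The list of p53 targets and senescence genes was higher. Cdkn2b, a cell cycle inhibitor, rose 10.3-fold and Sesn2, a stress-induced regulator of mTORC1, 9.61-fold, while Sesn1 fell 2.71-fold. Of 20 members, 16 rose and 1 fell, with the same counts adjusted over the list alone (median 1.52, camera adjusted p = 8.84e-08, and adjusted p = 0.379 with an estimated correlation). The proliferation lists did not pass. Among 23 DNA replication genes 0 rose and 5 fell, and among 24 mitosis genes 0 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.319 and 0.532). Mcm5 fell 2.13-fold and Bub1b 2.46-fold. Pola1 fell 1.95-fold but did not pass without WT 2, KO 1 or KO 2 (edgeR adjusted p = 0.216, 0.0649 and 0.128), and Kif11 fell 2.08-fold but did not pass without WT 1 or KO 1 (edgeR adjusted p = 0.0607 and 0.0701). Without WT 1, 1 replication gene rose. Without WT 2 or KO 2, 1 replication gene fell, and without WT 2 or KO 1, 2 mitosis genes fell. With upper quartile scaling 8 replication genes fell.

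Matrix remodelling genes showed large rises. Mmp13, a collagenase, had 0 counts in wild type and was at least 92.9-fold higher, at 35.6 ± 14.8 CPM. Mmp10 had 1 count in wild type and a pooled ratio of 84.2 (95% interval 14.8 to 3350), with a log2 change of 6.13 that was 5.40 without WT 1 and 8.68 without WT 2. Of 21 matrix protease and remodelling genes, 18 rose and 0 fell, and 20 rose and 0 fell adjusted over the list alone (median 2.57, camera adjusted p = 4.01e-14, and adjusted p = 0.379 with an estimated correlation). Lox rose 46.6-fold, from 12.2 ± 2.12 to 573 ± 64.2 CPM, and the activin subunit Inhba 24.8-fold. Both belong to the mesenchymal transition list, in which 15 of 18 genes rose and 1 fell, with the same counts adjusted over the list alone (median 2.29, camera adjusted p = 5.51e-11, and adjusted p = 0.422 with an estimated correlation). The gene that fell, Zeb1, changed by -0.63 on the log2 scale and did not pass without WT 1, WT 2 or KO 2 (edgeR adjusted p = 0.0908, 0.0599 and 0.116), and 0 fell without any of these 3 libraries. Among 18 TGF-beta and BMP genes, 11 rose and 3 fell, with the same counts adjusted over the list alone (median 0.82, camera adjusted p = 0.00531, and adjusted p = 0.379 with an estimated correlation). Pmepa1, a TGF-beta target, rose 9.02-fold, Ltbp2 5.47-fold, and the BMP antagonist Grem1 fell 15.1-fold. Bmp4 fell 2.09-fold but did not pass without WT 1, KO 1 or KO 2 (edgeR adjusted p = 0.247, 0.091 and 0.197), and without KO 1 or KO 2 1 gene of this list fell. The fibroblast genes had a median log2 change of 1.85 in these libraries.

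Macrophage genes rose and lymphocyte genes fell. The Fc receptor genes Fcgr3 and Fcgr1 rose 26.2-fold and 23.0-fold, Fcgr3 from 18.5 ± 6.82 to 484 ± 201 CPM. Of 21 macrophage and monocyte genes, 19 rose and 0 fell, and 20 rose and 0 fell adjusted over the list alone (median 3.12, camera adjusted p = 5.12e-20, and adjusted p = 0.379 with an estimated correlation). All 16 tested T and NK cell genes fell, 16 also adjusted over the list alone (median -5.04, camera adjusted p = 3.64e-25, and adjusted p = 0.379 with an estimated correlation). Cd8a fell 93.2-fold, from 118 ± 22.6 to 1.21 ± 0.575 CPM, and Nkg7, with 2 counts in the libraries labelled knockout, had a pooled ratio of 99.9 (95% interval 27.2 to 833). All 14 B cell and plasma cell genes fell, 14 also adjusted over the list alone (median -4.12, camera adjusted p = 4.39e-16, and adjusted p = 0.379 with an estimated correlation). Fcer2a fell 40.7-fold and Ighd 40.4-fold. Without KO 1 the T and NK median was -5.66 and the B cell median -4.96. Without KO 1 the log2 changes of Nkg7 and Ighd were -9.42 and -6.27, against -6.44 and -5.34 with all libraries, and without KO 2 they were -5.35 and -4.70.

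Genes of other tissue components also differed. Of 21 fibroblast and stellate cell genes, 15 rose and 2 fell, and 15 rose and 3 fell adjusted over the list alone, with Mfap5 up 13.2-fold and Pdpn 9.46-fold (camera adjusted p = 4.92e-07, and adjusted p = 0.499 with an estimated correlation). Of 12 smooth muscle genes, 1 rose and 10 fell, with the same counts adjusted over the list alone (median -1.84, camera adjusted p = 0.00166, and adjusted p = 0.609 with an estimated correlation). Myh11, smooth muscle myosin, fell 5.61-fold and Lmod1 6.12-fold, while the pericyte proteoglycan Cspg4 rose 8.28-fold. Desmin (Des), in both lists, fell 3.62-fold, did not pass without WT 1 (edgeR adjusted p = 0.0566) and changed by -2.57 instead of -1.86 without KO 1. Thy1 fell 1.63-fold and did not pass without WT 2 or KO 2 (edgeR adjusted p = 0.0883 and 0.0522). Without WT 1, 6 smooth muscle genes and 1 fibroblast gene fell, and without KO 2, 1 fibroblast gene fell. Of 14 endothelial genes, 0 rose and 10 fell, with the same counts adjusted over the list alone (median -0.95, camera adjusted p = 0.00164, and adjusted p = 0.470 with an estimated correlation), Pecam1 2.76-fold and Kdr 2.73-fold. Of 9 Schwann and neural genes, 0 rose and 7 fell, with the same counts adjusted over the list alone (median -2.37, camera adjusted p = 0.000316, and adjusted p = 0.380 with an estimated correlation), Ngfr 11.5-fold and Prph 8.98-fold. That median was -1.57 without WT 1 and -3.001 without WT 2, and 4 neural genes fell without KO 1 or KO 2.

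Among 8 mesothelial genes 3 rose and 0 fell, with the same counts adjusted over the list alone (median 1.16, camera adjusted p = 0.033, and adjusted p = 0.613 with an estimated correlation). Mesothelin (Msln) rose 40.8-fold, from 6.63 ± 2.38 to 275 ± 13.4 CPM. Wt1 rose with a log2 change of 3.001 that was 4.57 without WT 1, 2.20 without WT 2 and 2.60 without KO 1 (edgeR adjusted p = 0.0813). The mesothelial list did not pass without WT 2 (median 1.05, camera adjusted p = 0.107) or without KO 1 (-0.67, camera adjusted p = 0.349), and its median was 1.81 without KO 2. Among 8 adipocyte genes 4 rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0619, and 0.00771 with no filter). The fat cell hormone Adipoq, at 0 counts in wild type, was at least 13.1-fold higher. With upper quartile scaling 1 adipocyte gene fell. Among 8 neutrophil genes 4 rose and 2 fell, with the same counts adjusted over the list alone (median 0.80, camera adjusted p = 0.373). Mmp8 rose 8.21-fold but did not pass without KO 1 (edgeR adjusted p = 0.0688). Ltf fell 15.7-fold (log2 change -3.97) and S100a9 4.47-fold (-2.16). Ltf changed by -3.38 without WT 1 and did not pass without KO 1 or KO 2 (edgeR adjusted p = 0.0735 and 0.0596), nor with the replicate number as a block (-3.90, edgeR adjusted p = 0.142). S100a9 did not pass without WT 1, WT 2 or KO 2 (edgeR adjusted p = 0.0557, 0.0567 and 0.121, log2 change -1.38 without KO 2), and changed by -3.49 without KO 1. Without WT 1 or KO 1, 1 neutrophil gene fell, and without KO 2, 0 fell. The list's median was -0.43 without WT 1, -0.92 without WT 2, -3.49 without KO 1 and -0.64 without KO 2. The filter admitted 9, 10, 11 and 11 members in these runs, against 8 with all libraries. These medians therefore do not cover the same genes. Of 6 erythrocyte genes 0 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.244). Without KO 2, 0 fell, and without KO 1 the list passed with 2 that fell (median -3.59, camera adjusted p = 0.00381). Only 2 mast cell genes were tested, and Kit stood at 48.5 ± 6.00 and 24.2 ± 15.2 CPM (edgeR adjusted p = 0.126). Kit passed without KO 2 (log2 change -1.81, edgeR adjusted p = 0.00286).

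**Figure D2:**
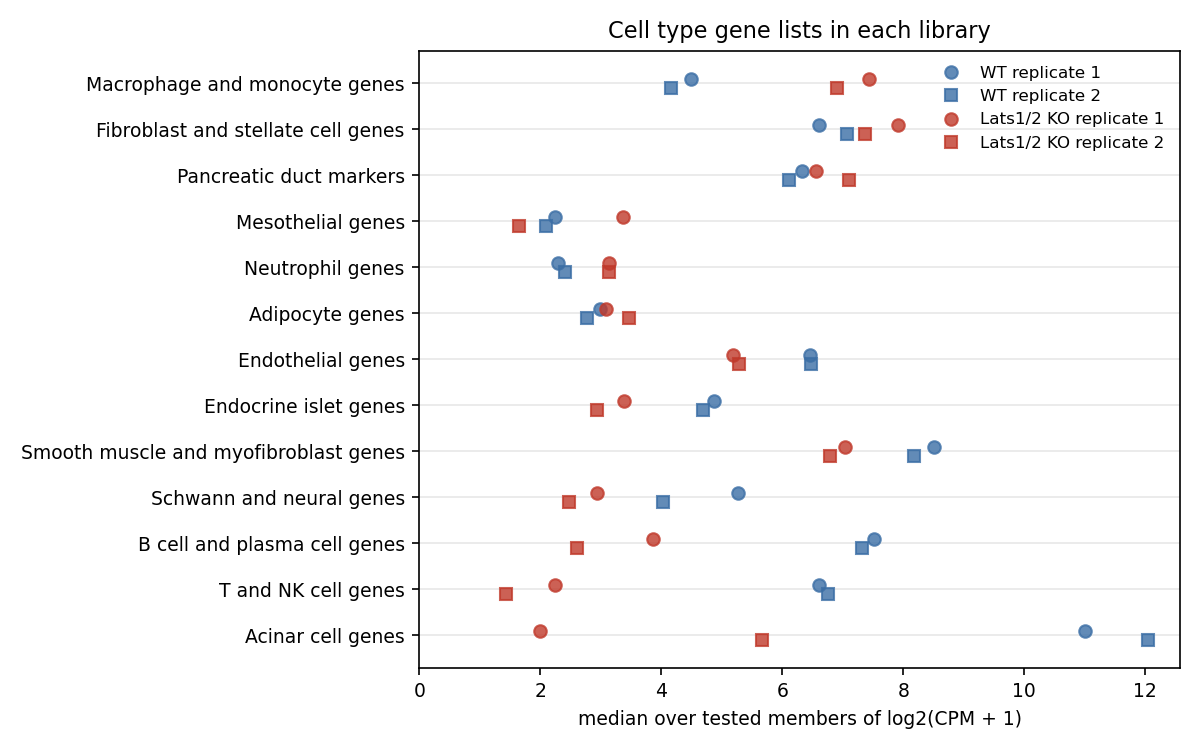
Median log2(CPM + 1) over the tested members of each cell type list, with 1 point per library. The T and NK cell and B cell lists separate the groups, with medians of -5.04 and -4.12 for the log2 change, and the acinar list differs between the 2 libraries labelled knockout.

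Acinar cell genes were low and uneven in the libraries labelled knockout. The list took 7.77% and 12.74% of the counts in WT 1 and WT 2, against 0.03% in KO 1 and 0.72% in KO 2. Its median log2 change was -5.63, or -5.62 with the gene at 0 counts set to its bound (camera adjusted p = 5.99e-06, and adjusted p = 0.621 with an estimated correlation). Of 28 tested members 0 rose and 4 fell, with the same counts adjusted over the list alone. Without KO 1, 23 fell and 1 rose (median -4.67), and without KO 2, 24 of 27 fell (median -9.03). In these runs the spread comes from the wild-type libraries alone. With the replicate number as a block 7 fell and 1 rose. The amylase Amy2a5, at 0 counts in the libraries labelled knockout, was at least 49.6-fold lower, with a fitted log2 change of -8.97 that was -8.35 without WT 2. Ctrc, with 3 counts there, had a pooled ratio of 110 (95% interval 37.1 to 536), and its log2 change of -6.61 was -5.87 without WT 2, -5.79 without KO 1 and -9.94 without KO 2.

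Among 18 endocrine islet genes 2 rose and 8 fell, and 2 rose and 11 fell adjusted over the list alone (median -1.77, camera adjusted p = 0.00429, and adjusted p = 0.529 with an estimated correlation). Ins2 fell 17.7-fold, from 884 ± 341 to 50.1 ± 9.45 CPM, and the glucose transporter Slc2a2, with 1 count in the libraries labelled knockout, had a pooled ratio of 244 (95% interval 43.2 to 9690). Nkx6-1 rose 4.98-fold and did not pass without WT 1, KO 1 or KO 2 (edgeR adjusted p = 0.104, 0.0816 and 0.216, log2 change 1.65 without WT 1 against 2.31 with all libraries), and changed by 4.05 without WT 2. Without WT 1, 14 islet genes fell, without KO 2, 5 fell, and without WT 1, KO 1 or KO 2, 1 rose. The islet median was -2.59 without KO 1. The log2 change of Slc2a2, -7.62, was -6.86 without WT 1, -6.92 without KO 1 and -9.62 without KO 2.

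Of 15 metaplasia genes 3 rose and 5 fell, and 5 rose and 5 fell adjusted over the list alone (median -0.46, camera adjusted p = 0.0474, and adjusted p = 0.640 with an estimated correlation). The mucin Muc6 fell 36.6-fold, and Agr2, with 2 counts in the libraries labelled knockout, had a pooled ratio of 77.2 (95% interval 20.9 to 645). Ctse, a gastric protease, rose 6.73-fold, and Anxa10, with 2 counts in wild type, had a pooled ratio of 20.3 (95% interval 5.37 to 172). The list did not pass without KO 1 (median 0.49, camera adjusted p = 0.990), with upper quartile scaling (-0.67, camera adjusted p = 0.0828) or with no filter (0.33, camera adjusted p = 0.0576). Its median was 0.18 without WT 2 and -2.42 without KO 2, and 5 rose without WT 1 and 8 fell without KO 2. The log2 change of Anxa10, 4.25, was 3.46 without WT 1, 7.67 without WT 2 and 3.81 without KO 1 (edgeR adjusted p = 0.0766). That of Agr2, -6.12, was -5.34 without KO 1 and -8.94 without KO 2, and that of Ctse, 2.75, was 2.12 without KO 2. With the replicate number as a block, Ctse did not pass (2.66, edgeR adjusted p = 0.068).

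Of 9 squamous and basal genes 4 rose and 2 fell, and 5 rose and 2 fell adjusted over the list alone (median 2.26, camera adjusted p = 0.785). Dsc3, a desmosomal cadherin, fell 51.0-fold and Ly6d, a gene of B cell precursors and keratinocytes, 12.9-fold. Pkp1, with 2 counts in wild type, had a pooled ratio of 70.0 (95% interval 19.1 to 582) and a log2 change of 6.00 that was 5.21 without WT 1 and 9.42 without WT 2. Dsc3 changed by -5.67 on the log2 scale and by -6.35 without KO 1. Ivl rose 18.9-fold but did not pass without WT 1, WT 2 or KO 2 (edgeR adjusted p = 0.303, 0.331 and 0.0545). Its log2 change of 4.24 was 4.99 without KO 1 and 2.55 without KO 2. It did not pass with limma voom (adjusted p = 0.275). Without KO 2, 2 genes of this list rose.

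Among 26 chemokines and cytokines 14 rose and 4 fell, and 16 rose and 4 fell adjusted over the list alone (median 1.30, camera adjusted p = 0.000981, and adjusted p = 0.529 with an estimated correlation). Interleukin 1 alpha (Il1a) rose 33.9-fold, from 1.97 ± 0.0701 to 67.9 ± 22.1 CPM. The neutrophil attractant Cxcl3, with 3 counts in wild type, had a pooled ratio of 29.3 (95% interval 9.78 to 144), and its log2 change of 4.80 was 3.99 without WT 1 and 8.76 without WT 2. Cxcl12 fell 5.30-fold and Ccl5, a chemokine made by T cells, 8.90-fold, with a log2 change of -3.15 that was -3.76 without KO 1. The macrophage list rose and the T and NK cell list fell in the same libraries, with medians of 3.12 and -5.04. Interferon-stimulated genes split, with 6 of 25 higher and 7 lower, and the same counts adjusted over the list alone (camera adjusted p = 0.542). Rsad2 rose 5.92-fold and Ifi44 2.82-fold, while the immunoproteasome subunit Psmb9 fell 5.96-fold. Without KO 1, 3 of these rose, and upper quartile scaling gave 2 that rose and turned the median from 0.09 to -0.10. The interferon median was 0.24 without WT 2 and 0.13 without KO 2, both with an upward set test, while the full data gave a downward one.

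NF-kB genes did not pass as a list, with 2 of 18 higher and 2 lower, and 1 higher and 2 lower adjusted over the list alone (median 0.15, camera adjusted p = 0.889). Tnfaip2 rose 3.02-fold, Traf1 fell 4.27-fold and Birc3 1.63-fold. Rela rose 1.39-fold but did not pass in any of the 4 runs without a library (edgeR adjusted p = 0.066 to 0.265), nor with RLE or upper quartile scaling (edgeR adjusted p = 0.0566 and 0.204). Birc3 did not pass without WT 2 (edgeR adjusted p = 0.0743). Without WT 1, WT 2 or KO 1, 1 gene of this list rose, and without WT 2, 1 fell. Upper quartile scaling gave 1 that rose, 4 that fell and a median of -0.04, and RLE scaling 1 that rose and 3 that fell. Among 12 Wnt targets 3 rose and 3 fell, with the same counts adjusted over the list alone (median -0.06, camera adjusted p = 0.210, and 0.0107 with the stricter filter). Lef1 fell 36.5-fold and Tcf7 11.3-fold, both also transcription factors of T cells. Sp5, with 2 counts in wild type, had a pooled ratio of 25.4 (95% interval 6.77 to 214). Lgr5 rose 6.64-fold but did not pass without KO 1 or KO 2 (edgeR adjusted p = 0.0973 and 0.0633), and without either, 1 Wnt target rose and 2 fell.

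Among 13 Notch genes 3 rose and 2 fell, with the same counts adjusted over the list alone (median -0.12, camera adjusted p = 0.822). The ligand Jag1 rose 2.96-fold, not passing without KO 2 (edgeR adjusted p = 0.0652), and the endothelial ligand Dll4 fell 2.91-fold. Heyl and Hey2 changed by 0.89 and -1.63 on the log2 scale and passed in none of the 4 runs without a library (edgeR adjusted p = 0.0603 to 0.251 and 0.111 to 0.239). Heyl also did not pass with upper quartile scaling (edgeR adjusted p = 0.102). Without WT 1, 1 Notch gene rose. Without KO 1, 1 rose and 1 fell, without WT 2, 1 fell, and without KO 2, 0 rose. Upper quartile scaling gave 1 that rose and 3 that fell. The Notch median was 0.22 without WT 2.

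Glycolysis and hypoxia genes were higher. The lactate transporter Slc16a3 rose 9.10-fold and hexokinase 2 (Hk2) 7.38-fold, from 36.8 ± 2.77 to 271 ± 32.6 CPM. Of 18 glycolysis genes 11 rose and 1 fell, with the same counts adjusted over the list alone (median 0.74, camera adjusted p = 0.00389, and adjusted p = 0.470 with an estimated correlation). Without WT 2, 6 rose and 0 fell, and upper quartile scaling gave 9 that rose and 3 that fell. The gene that fell, Pfkp, changed by -0.56 on the log2 scale and did not pass without WT 2, KO 1 or KO 2 (edgeR adjusted p = 0.175, 0.0595 and 0.0883), and 0 fell without any of these 3. Carbonic anhydrase 9 (Car9) rose 9.58-fold and Mxi1 4.44-fold. Of 14 hypoxia genes 9 rose and 0 fell, with the same counts adjusted over the list alone (median 0.92, camera adjusted p = 0.00113, and adjusted p = 0.379 with an estimated correlation).

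Oxidative phosphorylation genes did not pass as a list, with 1 of 26 higher and 1 lower, and 0 higher and 0 lower adjusted over the list alone (median 0.02, camera adjusted p = 0.889). Sdha changed by -0.63 on the log2 scale and did not pass without WT 1, KO 1 or KO 2 (edgeR adjusted p = 0.203, 0.0604 and 0.105). Without KO 1, 0 genes passed, without WT 2, 0 rose, and without WT 1 or KO 2, 0 fell. Upper quartile scaling gave 0 that rose and a median of -0.18, and the median was -0.08 without KO 1. Of 21 unfolded protein response genes 3 rose and 4 fell, with the same counts adjusted over the list alone (median 0.04, camera adjusted p = 0.957). Atf6 rose 2.10-fold and Creld2 fell 2.21-fold. Trib3 rose 3.14-fold and Sdf2l1 fell 2.00-fold. Trib3 did not pass without WT 2, KO 1 or KO 2 (edgeR adjusted p = 0.182, 0.0988 and 0.239) or with upper quartile scaling (edgeR adjusted p = 0.0614), and its log2 change of 1.65 was 2.70 without WT 1 and 1.01 without WT 2. Sdf2l1 did not pass without WT 2, KO 1 or KO 2 (edgeR adjusted p = 0.193, 0.105 and 0.0717). Without WT 2, 1 unfolded protein response gene rose and 2 fell. Without KO 1, 2 fell, and without KO 2, 1 rose and 1 fell. Upper quartile scaling gave 1 that rose and a median of -0.15.

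Of 19 cholesterol synthesis genes 3 rose and 1 fell, and 2 rose and 1 fell adjusted over the list alone (median 0.25, camera adjusted p = 0.537). Idi1, an isomerase of isoprenoid synthesis, changed by -0.84 on the log2 scale and did not pass without WT 1 or KO 1 (edgeR adjusted p = 0.0654 and 0.0681), when 0 fell. Without WT 2, 1 rose and 2 fell, as with upper quartile scaling. Of 26 cilium genes 6 rose and 2 fell, with the same counts adjusted over the list alone (median 0.40, camera adjusted p = 0.342). The polycystin gene Pkd2 rose 3.04-fold, while the intraflagellar transport genes Ift80 and Ift140 fell 4.17-fold and 2.07-fold. Bbs5 rose 3.45-fold and passed in none of the 4 runs without a library (edgeR adjusted p = 0.118 to 0.278), nor with upper quartile scaling (edgeR adjusted p = 0.0522). Without WT 1, 4 cilium genes fell, and without KO 1, 3 rose.

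Of 30 ribosomal protein genes 0 rose and 26 fell, and 27 fell adjusted over the list alone (median -0.74, camera adjusted p = 0.00164, and adjusted p = 0.740 with an estimated correlation). Rps16 fell 2.23-fold and Rplp1 2.22-fold. Without WT 1, 7 fell, and without WT 2, 5 fell. Of 13 mitochondrially encoded genes 0 rose and 1, mt-Cytb, fell, and 0 fell adjusted over the list alone (median -0.30, camera adjusted p = 0.662). It did not pass without WT 1, KO 1 or KO 2 (edgeR adjusted p = 0.392, 0.053 and 0.167). Without WT 1, 0 mitochondrial genes fell, without WT 2, 3 fell, and without KO 2, 4 rose and 0 fell. Mitochondrial genes that fell numbered 2 with upper quartile scaling, and the block gave 1 that rose and 4 that fell. The mitochondrial chromosome took 3.26% and 2.18% of the counts in WT 1 and WT 2 and 2.67% and 1.93% in KO 1 and KO 2.

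**Figure D3:**
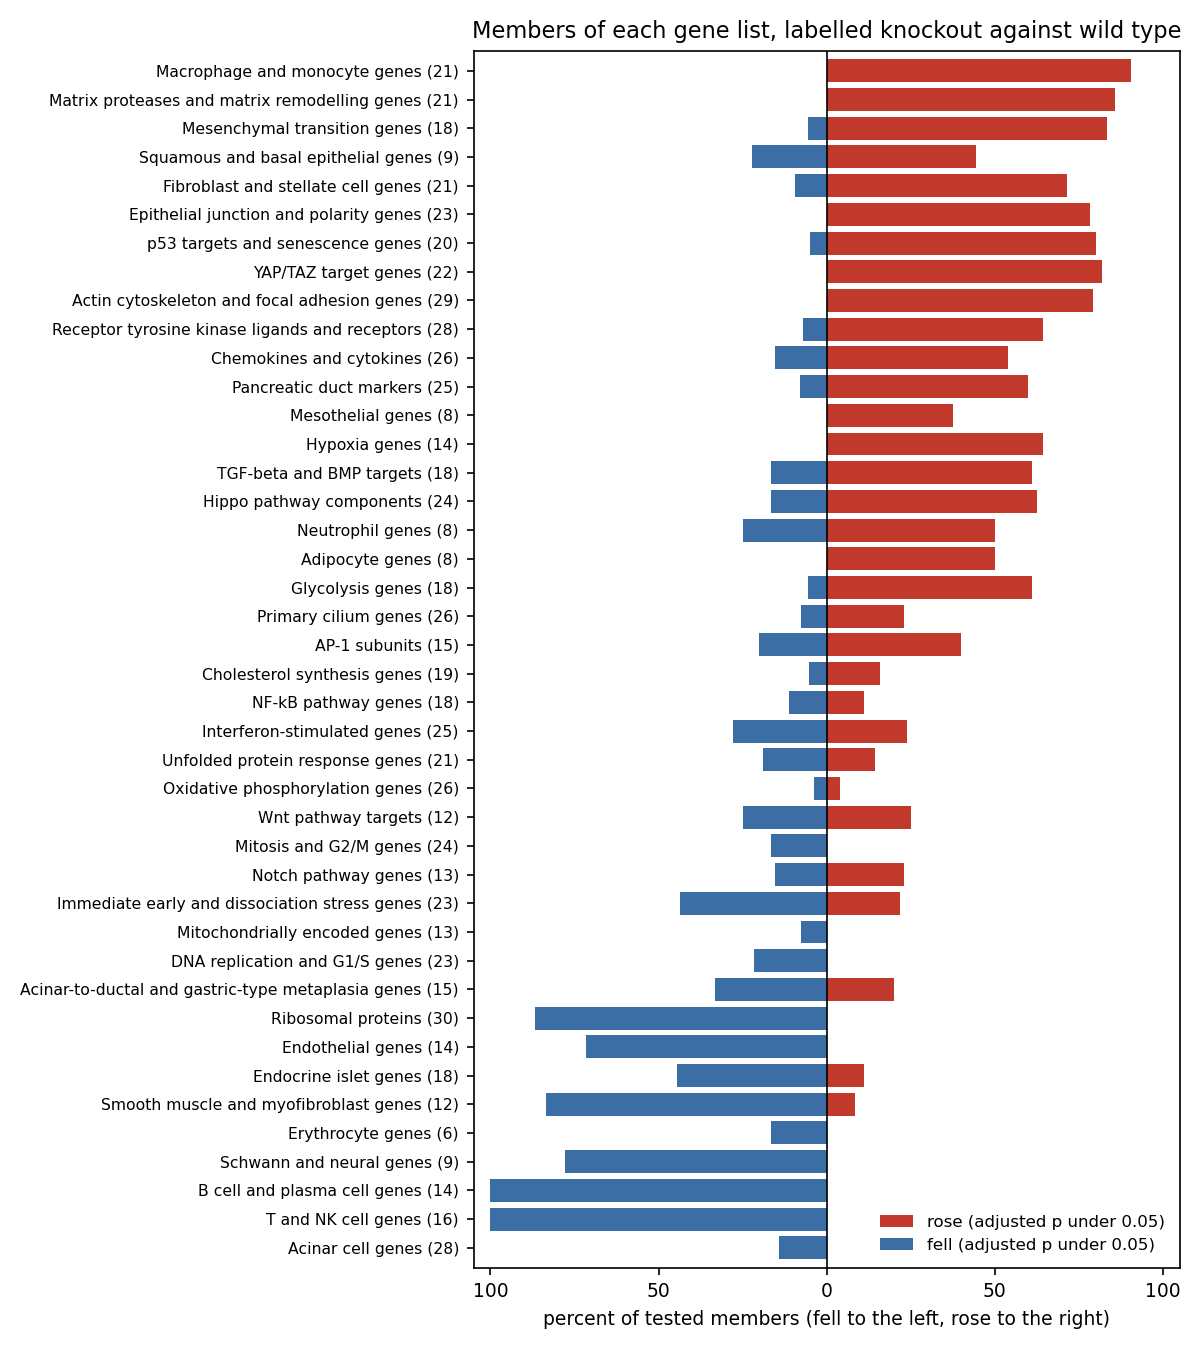
Percent of the tested members of each list (number tested in brackets) that rose, to the right, or fell, to the left, at an edgeR adjusted p under 0.05, ordered by median log2 change. Macrophage genes (19 of 21 rose) stand at one end, and the T and NK cell genes (16 of 16 fell) and B cell genes (14 of 14 fell) near the other.

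In all, 25 of 42 tested lists passed camera, 16 upward and 9 downward, and 0 passed with an estimated correlation, where the test has 2 degrees of freedom. The 8 largest rises by the fixed rule were Cfd, Mmp13, Saa3, Clec4d, Erfe, Tarm1, Ifi202b and Fst. All but Fst had 0 counts in wild type, and they were at least 98.7, 92.9, 60.2, 56.6, 35.8, 34.6 and 31.2-fold higher in that order. Cfd is the complement factor adipsin, Saa3 an acute phase protein, and Clec4d and Tarm1 are receptors of myeloid cells. Fst, the activin antagonist follistatin, had 2 counts in wild type and a pooled ratio of 240 (95% interval 66.1 to 1980). Its log2 change of 7.76 was 6.98 without WT 1 and 11.19 without WT 2. Without KO 1, the fitted log2 changes of Cfd and Saa3 were 9.90 and 9.14 against 10.51 and 9.80 with all libraries.

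The 8 largest falls were Fut7, Amy2a5, Apol7c, Serpini2, Aqp12, Slc2a2, Cd226 and Slc39a5. Fut7, a fucosyltransferase that builds selectin ligands, had 0 counts in the libraries labelled knockout and was at least 62.9-fold lower, and Amy2a5 at least 49.6-fold lower. Apol7c fell 322-fold, from 212 ± 75.1 to 0.665 ± 0.483 CPM, and Serpini2, a pancreatic serpin, 227-fold. The remaining genes had 1 count there, with pooled ratios of 284 for Aqp12, an acinar aquaporin (95% interval 50.4 to 11300), 244 for Slc2a2 (43.2 to 9690), 219 for the lymphocyte receptor Cd226 (38.8 to 8710) and 201 for the zinc transporter Slc39a5 (35.6 to 8000). Without KO 1 and without KO 2 in turn, log2 changes were -9.24 and -7.64 for Apol7c (-8.33 with all libraries), -6.97 and -12.80 for Serpini2 (-7.83), and -7.04 and -9.75 for Aqp12 (-7.76). They were -6.92 and -9.62 for Slc2a2 (-7.62, and -6.86 without WT 1), -6.68 and -9.38 for Cd226 (-7.39), and -9.41 and -6.25 for Slc39a5 (-7.27). Amy2a5 changed by -8.97, and by -8.35 without WT 2.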

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

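The run without the ribosomal RNA-like models was chosen after the data were seen. The genes changed between Lats1/2 KO and WT numbered 4206 to 4608 when 1 library was left out (genes higher in Lats1/2 KO 2265 to 2449, genes lower in Lats1/2 KO 1867 to 2276) and 3575 with glmTreat against a fold of 1.5 (1791 higher, 1784 lower), which tests a stricter null. Lats1 ranged from 0.20 to 0.56 and Lats2 from 0.17 to 0.63 on the log2 scale, Lats2 passing without KO 2, and with no filter at 0.47; the cause was not tested. With a replicate block, 6656 genes changed, including 5847 of the 5909, and 25 lists passed; same-numbered libraries correlated at 0.035 in their deviations, so the numbers were not taken to pair the samples. With the block, of 165 genes followed singly, 2 no longer passed (Ltf, Ctse) and 2 newly passed (Ankrd1, H2-DMa).

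Of 158 such genes past the threshold, 36 did not pass without at least 1 library, and 0 of the 165 reversed under any setting in which they were tested. Those no longer passing numbered 15 with DESeq2 (Batf, Car2, Nkx6-1, S100a9, Pola1, Zeb1, Fgfr2, Lgr5, Heyl, Hey2, Bmp4, Pfkp, Trib3, Sdf2l1 and Bbs5), 6 with upper quartile scaling, 3 with limma voom, 3 with the stricter filter (which left 11 of the 165 untested), 2 with no filter, and 1 each with RLE scaling and with scaling without the acinar list and the 100 most abundant genes.

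The YAP/TAZ target genes kept a median of 1.277 to 1.499 when 1 library was left out. With an estimated correlation their call was lost at the same median of 1.37 and 0 lists passed, in a run with 2 degrees of freedom. Fry, which tests each list against no change rather than against other genes, passed 15 lists. These include the adipocyte list, which camera did not call (fry adjusted p = 0.0321, camera adjusted p = 0.0619). Besides the duct and epithelial junction lists, camera calls that did not pass fry were the acinar, islet, fibroblast, smooth muscle and mesothelial lists. Their fry adjusted p-values were 0.0751, 0.0785, 0.0588, 0.0751 and 0.121 in that order. Nor did the Schwann, metaplasia, chemokine and ribosomal protein lists pass (fry adjusted p = 0.0588, 0.138, 0.0727 and 0.057). The AP-1 subunits passed with no filter (0.35) and ranged from 0.25 to 0.57 with 1 library left out. Leaving out 1 library gave 24 to 25 lists. Lists that did not pass changed the direction of their set test, and the cause was not tested: Unfolded protein response genes with the replicate block (median 0.022), upper quartile scaling (-0.155) and the stricter filter (-0.056), and 0.007 to 0.115 with 1 library left out; NF-kB pathway genes with upper quartile scaling (-0.044) and the stricter filter (0.084), and 0.10 to 0.27; Oxidative phosphorylation genes likewise (-0.178 and -0.049), and -0.077 to 0.135. With 1 library left out, medians ranged from -0.722 to -0.083 for Mitochondrially encoded genes, -3.49 to -0.43 for Neutrophil genes, -0.15 to 0.24 for Interferon-stimulated genes, -0.35 to 0.22 for Notch pathway genes, and -2.42 to 0.49 for Acinar-to-ductal and gastric-type metaplasia genes, which passed with all libraries. The filter was applied anew in each of these runs, so a list's tested members could differ. For example, 11 neutrophil genes were tested without KO 1 and 8 with all libraries. Depth limits genes near the floor of 3 counts, where only bounds or wide ratios can be given. A block crossing the replicate numbers was not run, since their deviations did not run in opposite directions, and pseudocounts and quantile normalization were not run, since the files hold counts.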

Other observations

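Of the tests below, those on the acinar genes, on the YAP/TAZ targets and on the dilution of lymphocyte genes were chosen after the results were seen, as were the lists of MHC class II, basement membrane, hepatocyte and Y-linked genes.

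Basement membrane genes were higher in the libraries labelled knockout: of 12 tested, 11 rose and 0 fell (median log2 change 1.82), and 11 rose adjusted over the list alone. Col4a1 and Col4a2, the main collagen IV chains, changed by 2.39 and 2.74 on the log2 scale and the laminin chain Lamb1 by 2.86 (edgeR adjusted p = 6.5e-05, 5.44e-05 and 1.55e-05). Lama4 did not pass without WT 2. The fibroblast and stellate cell list rose by a similar median, 1.85, in the same libraries, with 15 of 21 genes higher. MHC class II genes were lower: of 10 tested, 8 fell and 0 rose (median -2.31), and 8 fell adjusted over the list alone. Cd74, the invariant chain, changed by -1.89, H2-Ab1 by -2.10 and the class II transactivator Ciita by -4.83 (edgeR adjusted p = 0.000176, 6.04e-05 and 1.46e-05). H2-DMa was at -0.63 and did not pass (edgeR adjusted p = 0.121). It passed with the replicate number as a block, and was at -1.13 without KO 1. H2-Ob and H2-DMb2, class II genes typical of B cells, changed by -4.56 and -4.34 (edgeR adjusted p = 1.63e-05 and 1.18e-05). The B cell list fell in the same libraries (14 of 14 genes, median -4.12), while the macrophage list rose (19 of 21 genes, median 3.12).

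Hepatocyte genes stood apart in WT 1, where they took 1.07% of the counts with Alb, against 0.02% in WT 2 and 0.01% in each library labelled knockout; Alb was at 5788, 139, 3.22 and 1.13 CPM. Ribosomal RNA-like models took 3.45% and 6.81% of the counts in WT 1 and WT 2 and 2.50% and 0.54% in KO 1 and KO 2. Xist was at 99.5, 0, 172 and 136 CPM and the Y-linked Ddx3y at 55.8, 78.4, 31.4 and 37.7 CPM in WT 1, WT 2, KO 1 and KO 2. Of 4 Y-linked genes tested, 3 fell and 0 rose (median -1.17), with the same counts adjusted over the list alone, and Kdm5d changed by -2.20 (edgeR adjusted p = 0.000629). Xist and Y-linked transcripts were both present in WT 1, KO 1 and KO 2, which points to RNA of both sexes, and so of more than 1 animal, in each. WT 2 had Y-linked transcripts and 0 Xist counts, so the 2 wild-type libraries were not technical repeats of 1 RNA sample. The mix of sexes thus differed between libraries, with Y-linked genes lower in the libraries labelled knockout, and was not part of the fit.

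The fall of the T and NK cell and B cell lists was weighed against dilution by cell types that rose, which predicts that endothelial genes fall as far. The lymphocyte median minus the endothelial median was -3.55 on the log2 scale (95% bootstrap interval -4.30 to -2.87). Bootstrap intervals here and below resample genes, so they do not cover the spread between libraries. With 1 library left out, medians were -5.66 to -4.58 (T and NK cell), -4.96 to -3.58 (B cell) and -1.13 to -0.81 (endothelial). These values argue against dilution alone. Lymph node tissue in the wild-type preparations may also contribute: the lymph node stroma list had a median of -1.96 (-4.10 to -0.50, 11 genes), with 6 genes lower and 7 adjusted over the list alone, and the interval is too wide to decide. Named after their values were seen, the high endothelial venule genes Glycam1 and Madcam1 changed by -4.89 and -4.10 and Fut7, also among the 8 largest falls, had 0 counts in the libraries labelled knockout, while B3gnt3 and Bst1 stood at 0.29 and 0.22 and did not pass. Fewer lymphocytes in the tissue of the mice labelled knockout remains open and untested.

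The acinar genes were lower and uneven in the libraries labelled knockout. Scaling without the acinar list and the 100 most abundant genes left their median at -5.66 (-6.46 to -4.18), so normalization moved by these abundant transcripts is unlikely to account for the fall. Relative to the wild-type mean, 20 acinar genes with at least 100 counts in KO 2 ranged from 0.205% (Pnlip) to 41.4% (Try5) there and from 0.0218% (Pnlip) to 0.98% (Try5) in KO 1. Try5 is a trypsin, whose values are uncertain as for other near-identical genes. Ctrb1, the next highest, stood at 19.5% in KO 2 and 0.768% in KO 1. The log2 ratios of these 2 libraries to wild type correlated at 0.888, and the KO 2 to KO 1 ratio had a median of 25.3 (range 6.92 to 104). The SD of the KO 2 ratios was 7.78 times that of the wild-type pair (5.11 to 13.43), but this assumes the wild-type acinar profile and decides nothing, so acinar RNA carried over in different amounts and a change of the acinar cells themselves cannot be told apart.

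The rise of the YAP/TAZ target genes could reflect normalization or a higher share of epithelial RNA in the libraries labelled knockout. The lowest median of the list over 4 scalings was 1.18 (0.79 to 2.32), which argues against scaling moved by a few abundant genes. These scalings placed the median of all genes between -0.204 and -0.007, and all assume that most genes are unchanged. A shift shared by most genes was therefore not tested. The list's median minus that of the epithelial junction genes was -0.27 (interval -0.79 to 0.91), so a higher epithelial share and a response of the targets to a loss of LATS1 and LATS2, which these counts do not check, cannot be told apart from these lists. Ctgf rose by 5.25 on the log2 scale, but a single gene does not decide between them. The fibroblast and stellate cell list also rose in these libraries, with 15 of 21 genes higher and a median of 1.85. Its share of the RNA was not weighed against the rise of the YAP/TAZ targets.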
